A study of Mus musculus with 9 samples.

How the data were processed

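Polyadenylated RNA from mouse skin was extracted with a Qiagen miRNeasy kit and made into libraries with the IDT xGen Broad-Range kit, per the labels' protocols. The reads were aligned to mm39 with HISAT2 and counted per gene with featureCounts, per the submitters' processing notes. The deposited table holds raw counts per gene, not normalized, with 1 column per library, per the file headers. The versions of these tools, the gene annotation, the strand setting and whether reads or fragments were counted are not given in the sources used here. In the deposited count table the length of a gene equalled its whole span for 99.9% of the 54456 genes, so reads in introns were counted with those in exons. A gene that overlaps another, on either strand, or that shares sequence with a close copy (keratin-associated, small proline-rich, MHC and antibody genes among them) can therefore carry a count that belongs in part to another gene. Symbols and coordinates are those of the deposited table.

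The groups were taken from the treatment labels, with 3 libraries each. Total counts ran from 85962714 to 96740589 per library, and the tested genes held 99.96% of them. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 26081 of the 42688 genes with at least 1 count. Counts were scaled with TMM factors and fitted with edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group, all 9 libraries in the fit and the robust quasi-likelihood test. The common biological coefficient of variation was 0.0390. Adjusted p-values are Benjamini-Hochberg values over all tested genes, called under 0.05. Fold changes are given as log2 values with a standard error taken from the F statistic, and levels as CPM, counts scaled to a common library size, as mean ± SD over 3 libraries.

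Before the data were examined, 37 gene lists were fixed for skin, hair follicle and immune cell types and pathways, for other tissues that a skin sample can hold, and for handling and RNA quality. They were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Counts of list members that rose or fell use the adjustment over all tested genes, or over the list alone where that is said. Genes are named by a rule fixed at the same time. It takes the 8 highest and the 8 lowest log2 fold changes among called genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes and pseudogenes. It adds up to 4 members of each described list with the smallest p, and Il2, Ccl22, Ccl17, Foxp3, Il2ra, Ccr4, Cd8a, Ifng, Krt25, Krt71 and Krt85. Other genes named in the text, the V genes among them, were chosen after their values were seen, and so were the test of counts against a 2-fold change, the lists of clock and p53 target genes and the comparison of V genes with 1000 sets of other genes of nearby total count.

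The steps were tested on simulated counts for 25675 genes, drawn from the real means and library sizes with a set of genes changed by known amounts. For the loaded device against untreated skin, genes of at least 1 CPM changed 1.25-fold were recovered in 77.8% of cases, and those changed 1.5-fold, 2-fold or 4-fold in 100% of cases, with 0.0511% of unchanged genes called. For the loaded against the empty device the shares were 74.1%, 87.1%, 95.5% and 100%. With genes under 1 CPM included, the shares were 42%, 71.4%, 57.1% and 98% for the loaded device against untreated skin. Between the devices they were then 40%, 57.1%, 57.1% and 94%. The simulated spread was that fitted to these libraries, so the shares and the false calls leave out any spread between animals. In the simulation 25456 of the 25675 genes were unchanged with the loaded device, whereas 41.4% to 48.3% of genes were called in the real comparisons. The shares therefore do not show how the scaling and the calls behave where so many genes differ.

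Alternatives were other scalings (DESeq2 size factors, upper quartile, library size alone, TMM without keratin, muscle and mitochondrial genes), no filter and a stricter filter, the DESeq2 1.42.0 Wald test, limma-voom, no robust fit, only the 2 groups compared, the replicate number as a block, a skeletal muscle score as a covariate, a 2-fold minimum, and leaving out each library. Other splits of the same libraries were refitted to count how often they gave as large a result. A reference genome of another mouse build was not used here.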

Results

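Polyadenylated RNA from mouse skin was sequenced in 9 libraries, 3 from untreated lesions, 3 from lesions treated with microneedles that carried no drug (the empty device) and 3 from lesions treated with microneedles that carried IL-2 and CCL22 (the loaded device). The labels call the lesions AA-like, in a study of immune-mediated alopecia. Microneedles are short needles that bring a load into the skin. IL-2 is a T cell growth factor on which regulatory T cells depend, and CCL22 is a chemokine that attracts cells bearing the receptor CCR4. The total count per library ran from 85962714 to 96740589. Of the 54456 genes in the table, 26081 had enough counts to be tested, and a 3-group test with edgeR called 15440 of them at an adjusted p under 0.05.

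The 3 groups lay apart on the first 2 principal components, which held 33.4% and 25.2% of the variance. Libraries of 1 group lay closer to each other than to the others. The median squared difference between the counts of a pair of libraries was 1.90 to 3.91 times counting noise within groups (9 pairs) and 11.2 to 26.3 times counting noise between groups (27 pairs). The mean over genes was up to 12.8 times counting noise within groups and at least 96.0 times between them. Counting noise here takes all counts as independent. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

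**Figure D1:**
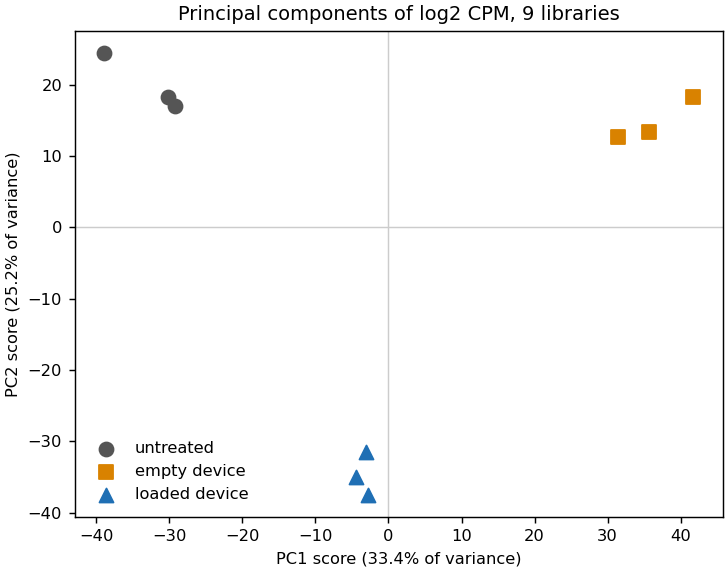
Scores of the 9 libraries on the first 2 principal components of log2 CPM, in arbitrary units, with 1 point per library, coloured by group. The untreated and empty-device libraries sit at opposite ends of PC1 (33.4% of the variance), and the loaded-device libraries sit apart from both on PC2 (25.2%).

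Some antibody V genes, the variable segments whose use differs between B cell clones, were high in 1 group. Of 32 V genes of antibody and T cell receptor loci, 3, 2 and 3 had at least 5 times the summed count of both other groups in the untreated, empty-device and loaded-device libraries. Others were alike across the groups, such as Ighv1-14 with 16, 19 and 20 counts in the untreated libraries, 14, 11 and 19 with the empty device and 20, 17 and 12 with the loaded device. The V genes named here were chosen after their values were seen. Ighv7-3 had 432, 467 and 466 counts in the untreated libraries, 3, 2 and 13 with the empty device and 5, 25 and 15 with the loaded device. Igkv8-30 had 127, 139 and 199 counts with the empty device, 11, 14 and 4 in the untreated libraries and 12, 11 and 16 with the loaded device. Igkv6-20 had 114, 123 and 175 counts with the loaded device, 5, 6 and 1 in the untreated libraries and 3, 0 and 1 with the empty device. V genes share sequence with each other, so the count of a single V gene is uncertain.

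**Figure D2:**
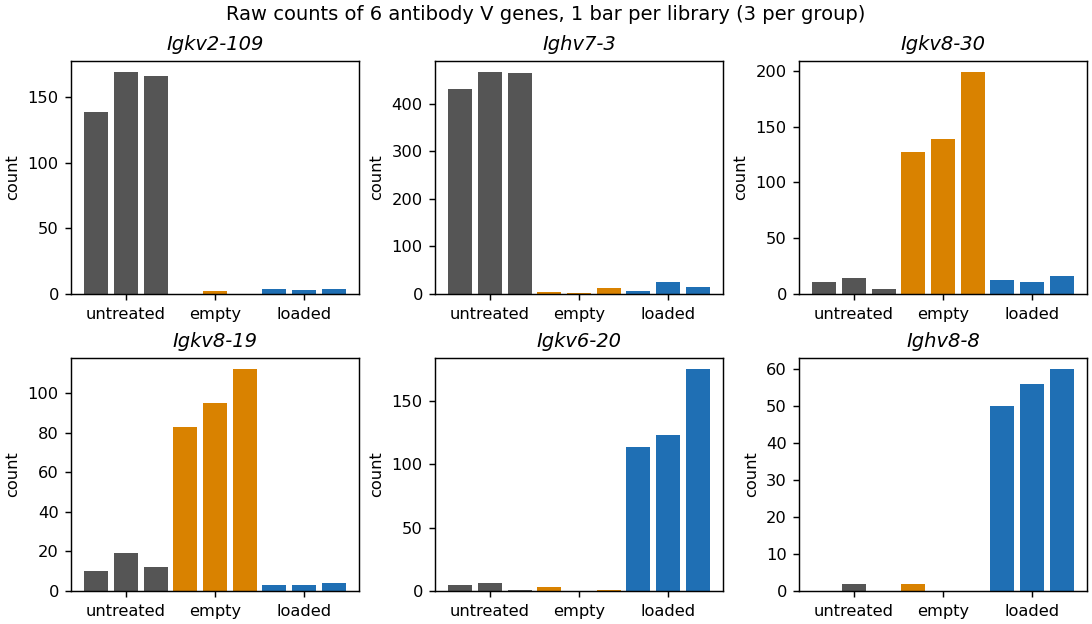
Raw counts (y axis) of 6 antibody V genes chosen for a high count in 1 group, with 1 bar per library and 3 libraries per group (x axis). Each gene is high in the 3 libraries of 1 group, such as Ighv8-8 with 50, 56 and 60 counts with the loaded device, and low in the other 6, where it has at most 2 counts.

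The genes of the 2 delivered proteins and of the cells they act on were read first in all groups. Levels are given in CPM, counts scaled to a common library size. Ccl22 stood at 7.77 ± 0.454 CPM in the untreated libraries, 4.30 ± 0.208 with the empty device and 11.8 ± 1.67 with the loaded device (mean ± SD, n = 3 libraries each), so that it was 2.75-fold higher with the loaded than with the empty device (log2 fold change 1.46, SE 0.085, edgeR adjusted p = 2.86e-12). Ccl22 lies on chromosome 8 from 95472218 to 95478327 in mm39. Ccl17, the gene of the other CCR4 ligand, fell with both devices, from 0.904 ± 0.154 CPM to 0.181 ± 0.0282 with the empty and 0.171 ± 0.0414 with the loaded device. Il2 transcripts were close to the detection limit in every group, at 0.225 ± 0.0850, 0.192 ± 0.0682 and 0.218 ± 0.0564 CPM in the same order. Foxp3, the master regulator of regulatory T cells, stood at 0.329 ± 0.0753, 0.261 ± 0.0411 and 0.288 ± 0.0952 CPM, and the log2 fold change between the loaded device and untreated skin was -0.20 (SE 0.29, edgeR adjusted p = 0.637), a difference not detectable at this depth. Ccr4 stood at 4.60 ± 0.0834, 4.77 ± 0.598 and 4.57 ± 0.392 CPM, with no call in any comparison. Ifng, the gene of interferon-gamma, fell from 0.229 ± 0.0588 CPM in untreated skin to 0.0550 ± 0.0411 with the empty and 0.0660 ± 0.0306 with the loaded device. It was also close to the detection limit, with raw counts of 21, 23 and 14, of 1, 9 and 6 and of 9, 5 and 4 in the same order. Its log2 fold changes against untreated skin were -2.01 (SE 0.49) with the empty and -1.78 (SE 0.48) with the loaded device. Cd8a and Il2ra, the genes of a cytotoxic T cell co-receptor and of the IL-2 receptor alpha chain, were lower with the loaded device than in untreated skin by edgeR, at log2 fold changes of -0.69 (adjusted p = 0.0346) and -0.59 (adjusted p = 0.0105). The Cd8a call was lost without loaded-device library 1 or 3 or untreated library 1 or 3 (log2 fold changes of -0.63, -0.66, -0.63 and -0.65), and the Il2ra call was lost without loaded-device library 1 or untreated library 3 (-0.46 and -0.47). The Cd8a call was also lost with library-size scaling, with no filter and by the DESeq2 Wald test (adjusted p = 0.0858, 0.0765 and 0.0789). Its log2 fold changes there were -0.56, -0.68 and -0.68. With the empty device Cd8a and Il2ra changed by -0.63 ± 0.26 (edgeR adjusted p = 0.0461) and -0.43 ± 0.18 (adjusted p = 0.0495). These calls were lost on leaving out 8 and 6 of the 9 libraries, each in turn, at log2 fold changes of -0.66 to -0.57 and -0.44 to -0.29. They were also lost under DESeq2, upper-quartile and library-size scaling (adjusted p of 0.0625 to 0.0961 for Cd8a and 0.0623 to 0.137 for Il2ra). With the replicate number as a block both were lost as well (log2 fold changes of -0.63 and -0.43, edgeR adjusted p = 0.0562 and 0.0541). The same held with no filter, by the DESeq2 Wald test, with only the 2 groups compared and with the muscle score as a covariate. The Ifng call with the empty device was lost with the skeletal muscle score as a covariate (log2 fold change -2.38, edgeR adjusted p = 0.341), although the fold change was not smaller. Krt85, a hair keratin gene, was not analysed here.

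**Figure D3:**
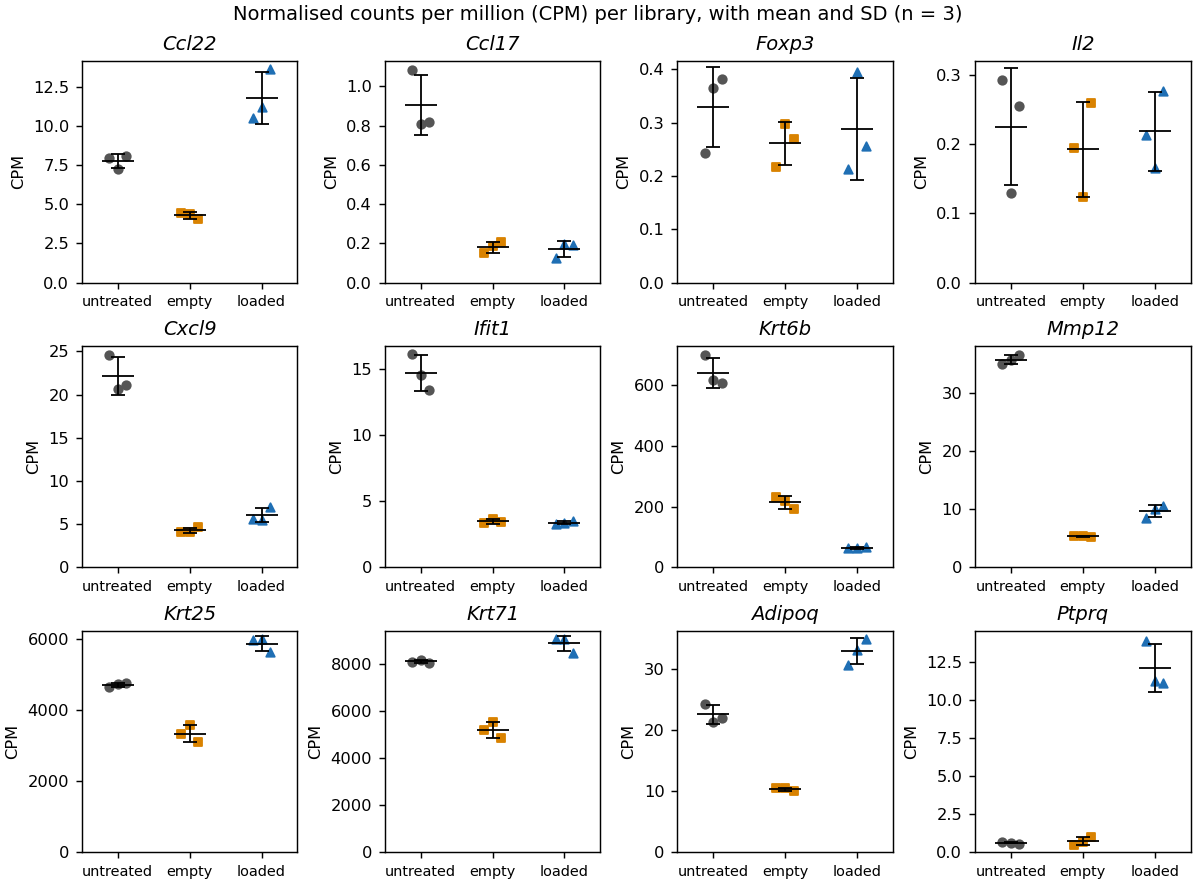
Normalised counts (CPM, y axis) of 12 genes in each library, by group (x axis), with 3 libraries per group; horizontal bars are means and whiskers are SDs. Ccl22 is highest with the loaded device (11.8 ± 1.67 CPM), Cxcl9, Ifit1 and Ccl17 are low with both devices, and Krt25 and Krt71 are lowest with the empty device.

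The loaded device was compared with untreated skin to ask how lesions that received IL-2 and CCL22 differed from lesions left alone. Genes of injured, hyperplastic epidermis were far lower with the loaded device. Krt6b, an injury-induced keratin, fell from 641 ± 50.1 to 63.5 ± 2.65 CPM (log2 fold change -3.34, SE 0.086, n = 3 libraries per group), and Krt16, another injury keratin, changed by -1.86 ± 0.060 (log2 fold change ± SE). Of the 24 tested injury-associated keratinocyte genes, 22 fell, none rose and 2 did not pass, with a median log2 fold change of -1.23. Adjusted over the list alone, 22 fell. Krt6a (-1.62), the serpin Serpinb3a (-2.07) and the cytokine gene Il24 (-2.70) led the list, whose camera adjusted p was 2.17e-38, against an adjusted p of 0.0618 with an estimated correlation. Krt6a and Krt6b are near-identical copies, so how the reads divide between them is uncertain. The epidermal differentiation list fell as well (19 of 24 lower, 2 higher, 20 lower adjusted over the list alone, median -0.54), with the protease gene Klk7 at -1.03 and the cornified envelope gene Hrnr at -1.05; its adjusted p was 0.0618 with an estimated correlation. Among the 8 genes with the lowest fold changes were also the protease inhibitor genes Wfdc12 (-3.71 ± 0.13) and Spink7 (-2.65 ± 0.13), the acute-phase gene Saa1 (-3.07 ± 0.13) and the protease gene Tmprss11d (-2.70 ± 0.092).

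Interferon-stimulated genes were lower with the loaded device. All 21 tested type I interferon genes fell, also adjusted over the list alone, with a median log2 fold change of -0.70; Ifit1 changed by -2.12 ± 0.074, Ifi44 by -1.73 ± 0.085 and Isg15 by -1.08 ± 0.056. Of the 21 interferon-gamma response genes, 16 fell and none rose (18 fell adjusted over the list alone), led by the T cell attracting chemokine genes Cxcl9 (-1.87 ± 0.086) and Cxcl11 (-2.47 ± 0.17). The adjusted p of the 2 lists was 0.0618 and 0.10 with an estimated correlation. MHC class I genes (14 of 17 lower, 1 higher, 14 lower adjusted over the list alone) and MHC class II genes (10 of 12 lower, none higher, 11 lower adjusted over the list alone) fell at medians of -0.37 and -0.52, among them the immunoproteasome gene Psmb9 (-0.59) and H2-Aa (-0.87). With an estimated correlation their adjusted p was 0.152 and 0.10.

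Macrophage and pan-T genes were lower with the loaded device. Of 19 macrophage genes, 16 fell and none rose, with a median of -0.59 (adjusted p = 0.0626 with an estimated correlation; 16 lower adjusted over the list alone); the complement gene C1qc changed by -0.75 ± 0.045 and Adgre1 by -0.84 ± 0.061. Of 19 pan-T genes, 12 fell, among them Trbc2 (-0.86 ± 0.058) and Cd3g (-0.73 ± 0.066), with a list median of -0.32 (adjusted p = 0.248 with an estimated correlation; 13 lower adjusted over the list alone). The cytotoxic list had 8 of 18 members lower and 0 higher (8 lower adjusted over the list alone), at a median of -0.46. Gzmb, which encodes granzyme B, fell by 3.56-fold and Xcl1 changed by -1.21 ± 0.18. The list did not pass (camera adjusted p = 0.169), but did, lower, with library-size scaling (0.0297). The regulatory T list did not pass either (camera adjusted p = 0.201), with 8 of 16 members lower, led by Tnfrsf18 (-0.62 ± 0.060) and Icos (-0.98 ± 0.19). The CCL22 axis list had 3 of 6 members lower and 1 higher (4 and 1 adjusted over the list alone), at a median of -0.72. It did not pass (camera adjusted p = 0.101), but did, lower, with library-size scaling (0.0397) and with the replicate number as a block (0.0391). The list of factors described as guardians of the immune privilege of the follicle did not pass (camera adjusted p = 0.570), in which Cd200 (-0.33 ± 0.037) and Igf1 (-0.37 ± 0.047) were among 4 lower members and Tgfb1 (0.17 ± 0.046) among 2 higher ones of 13. Ighg1, an antibody constant region gene, fell from 17.5 ± 0.592 to 2.44 ± 0.324 CPM, and the V gene Ighv7-3 fell from 5.37 ± 0.119 to 0.163 ± 0.109 CPM. Antibody genes did not fall as a group. The B and plasma cell list did not pass (camera adjusted p = 0.823), with 2 of 11 members lower, 0 higher and a median of -0.047. Other V genes were higher with the loaded device, such as Igkv6-20, at 114, 123 and 175 counts against 5, 6 and 1 in untreated skin. Fibroblast and matrix genes fell in 20 of 23 cases with none higher (21 adjusted over the list alone; adjusted p = 0.0618 with an estimated correlation), with the collagenase gene Mmp13 at -1.86 and Col1a1 at -0.69.

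Hair matrix and hair shaft genes rose, by smaller amounts. Of 23 hair matrix and growth phase regulators, 21 rose and none fell (22 adjusted over the list alone), with a median log2 fold change of 0.34; Lef1, which encodes a transcription factor of Wnt signalling in the matrix, changed by 0.64 ± 0.038 and Wnt10b by 0.73 ± 0.054. Of 26 hair keratin genes, 20 rose and 3 fell (21 and 4 adjusted over the list alone), with a median of 0.25; the inner root sheath keratins Krt25 and Krt71 changed by 0.32 ± 0.043 and 0.13 ± 0.042. Keratin-associated protein genes rose in 33 of 55 cases and fell in 7 (35 and 7 adjusted over the list alone; median 0.19), with Krtap19-1 at 0.42 and Krtap5-3 at -1.39. With an estimated correlation the adjusted p of these 3 lists was 0.152, 0.444 and 0.578. The Krt71 call was lost without loaded-device library 1 or 2 (log2 fold changes of 0.11 and 0.11). Melanocyte genes rose in 7 of 15 cases and fell in 4 (7 and 4 adjusted over the list alone; median 0.13; adjusted p = 0.536 with an estimated correlation). This camera call was lost without loaded-device library 1 or 2 or untreated library 2 or 3 (adjusted p = 0.0608, 0.0571, 0.0669 and 0.0510) and with a stricter filter (0.0674). The cell cycle list did not pass (camera adjusted p = 0.310). The dermal papilla list did not pass either (adjusted p = 0.0549), but did with DESeq2 or library-size scaling (0.0455 and 0.0297), with the skeletal muscle score as a covariate (0.0410) and without untreated library 1, empty-device library 1 or 3 or loaded-device library 3 (0.0432, 0.0449, 0.0418 and 0.0264). It also passed with the replicate number as a block (camera adjusted p = 0.0480). The skeletal muscle list did not pass (camera adjusted p = 0.0575), but did with DESeq2 scaling (0.0283). With the muscle score, built from its own genes, as a covariate it passed too. It also passed without empty-device library 1 or 3 or loaded-device library 2 or 3 (0.0161, 0.0169, 0.0395 and 0.0264). The replicate number as a block gave a call as well (camera adjusted p = 0.0412). Adipocyte genes rose in 8 of 15 cases and none fell (median 0.23; 9 higher and 1 lower adjusted over the list alone; adjusted p = 0.152 with an estimated correlation). The 8 genes with the highest fold changes were Ptprq, a receptor phosphatase gene at 4.32 ± 0.17, the slow muscle myosin gene Myh7 (1.91 ± 0.12), the monooxygenase gene Cyp2e1 (1.42 ± 0.063), the carboxylesterase gene Ces1f (2.39-fold), the immediate-early genes Fosb (2.29-fold) and Fos (1.03 ± 0.051), the ion transporter gene Slc12a1 (1.17 ± 0.062) and the gluconeogenesis gene Pck1 (1.06 ± 0.060). Ptprq lies on chromosome 10 from 107352910 to 107555912 in mm39.

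In all, edgeR called 11024 genes between the loaded device and untreated skin at an adjusted p under 0.05, of which 4950 were higher and 6074 lower (44.9% higher), and 501 reached a 2-fold change (84 higher, 417 lower). Of the 26081 genes, 52.7% did not overlap between the groups, where chance gives 10%. Scaling by library size alone moved the share of higher calls to 68.1% and the median of all genes by 0.13 on the log2 scale. Camera called 17 of 37 lists, of which 0 passed with an estimated correlation (11 at an unadjusted p under 0.05; fry called 30). Mitochondrially encoded transcripts made up 4.62 ± 0.0891% of counts in untreated skin, 3.37 ± 0.0544% with the empty and 3.83 ± 0.0622% with the loaded device, a measure of RNA quality that moved with the groups.

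The loaded device was compared with the empty device, which differs from it by the load. The labels do not tell the device apart from the animal or the skin sampled, so the contrast cannot be credited to the load alone. Hair shaft and hair matrix genes were higher with the loaded than with the empty device. Against untreated skin the hair keratin median was -0.51 with the empty and 0.25 with the loaded device. Of 26 hair keratin genes, 25 rose and none fell, with a median log2 fold change of 0.76 (25 adjusted over the list alone); Krt31 changed by 0.90 ± 0.039, Krt35 by 0.88 ± 0.039 and Krt25 by 0.82 ± 0.043 (n = 3 libraries per group). Keratin-associated protein genes, which build the hair shaft with the keratins, rose in 52 of 55 cases (53 adjusted over the list alone; median 0.74), such as Krtap19-1 (1.23 ± 0.043) and Krtap11-1 (1.08 ± 0.042); these genes share sequence and their single counts are uncertain. With an estimated correlation the adjusted p of the 2 lists was 0.0505 and 0.0721. The hair matrix list rose in 20 of 23 cases and fell in 1 (median 0.62; 20 adjusted over the list alone), with Lef1 at 0.89 and Msx2 at 0.79 (adjusted p = 0.0631 with an estimated correlation).

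Cell cycle, melanocyte, dermal papilla and adipocyte genes were higher as well. All 20 cell cycle genes rose (all 20 adjusted over the list alone), with a median of 0.59; Top2a changed by 0.79 ± 0.035 and Mki67, a marker of dividing cells, by 0.83 ± 0.037. Melanocyte genes rose in 14 of 15 cases with none lower (median 0.99; 14 adjusted over the list alone), with the pigment enzyme genes Dct at 0.99 and Tyr at 1.19. Dermal papilla genes rose in 13 of 17 cases and fell in 1 (median 0.55; 14 adjusted over the list alone), led by Corin (2.30-fold) and Wif1 (1.13 ± 0.055). Adipocyte genes rose in 12 of 15 cases and fell in 3 (median 0.62; 12 higher and 3 lower adjusted over the list alone); Adipoq, which encodes adiponectin, went from 10.3 ± 0.280 to 32.9 ± 2.14 CPM. The lower members were Car3 (-0.50), Slc2a4 (-0.51) and Acsl1 (-0.44), and the list made up 0.265 ± 0.0165% of counts with the empty and 0.275 ± 0.00568% with the loaded device. These 4 lists and the epidermal differentiation list passed with an estimated correlation as well (adjusted p = 0.0288 for each). Skeletal muscle genes moved the other way (17 of 20 lower, 2 higher, 17 lower adjusted over the list alone, median -0.62, adjusted p = 0.231 with an estimated correlation). That call was lost with the muscle score as a covariate (camera adjusted p = 0.0588), but the score is built from these same genes, so this is no separate check. These genes made up 1.72 ± 0.165% of counts with the empty device and 1.21 ± 0.0322% with the loaded device.

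Epidermal differentiation and injury genes were lower with the loaded device. Of 24 differentiation genes, 23 fell and 1 rose (23 lower adjusted over the list alone; median -0.76), among them Casp14 (2.29-fold lower), Krt1 (-1.08 ± 0.040) and Lor, which encodes the envelope protein loricrin (-1.02 ± 0.042). The injury list fell in 20 of 24 cases and rose in 2 (median -0.84; 20 adjusted over the list alone; adjusted p = 0.0813 with an estimated correlation), with Sprr2d at -1.67. Fibroblast and matrix genes fell in 16 of 23 cases and 4 rose (18 lower adjusted over the list alone; median -0.22). Macrophage genes fell in 10 of 19 cases and 1 rose (10 lower adjusted over the list alone; median -0.23). MHC class I genes fell in 9 of 17 cases and 0 rose (10 lower adjusted over the list alone; median -0.18). The adjusted p of these 3 lists was 0.238, 0.391 and 0.513 with an estimated correlation, and their camera calls were lost with the muscle score as a covariate (0.0770, 0.0770 and 0.110). MHC class II genes fell in 11 of 12 cases (median -0.57; 12 adjusted over the list alone; adjusted p = 0.0590 with an estimated correlation), with the invariant chain gene Cd74 at -0.75. Genes of common gamma chain cytokine signalling, the pathway of IL-2, fell in 11 of 16 cases and 1 rose (11 lower adjusted over the list alone; median -0.37; adjusted p = 0.0505 with an estimated correlation), including the negative regulator gene Socs3 (-0.48 ± 0.037) and Stat5b (-0.42 ± 0.038). Against untreated skin the same list was called higher with the empty device (6 of 16 higher and 3 lower, 7 and 3 adjusted over the list alone, median 0.081, camera adjusted p = 0.0181; adjusted p = 0.210 with an estimated correlation). That call was lost with the skeletal muscle score as a covariate (0.115). It did not pass with the loaded device against untreated skin (median -0.095, camera adjusted p = 0.281).

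The interferon-gamma response list did not pass between the devices (camera adjusted p = 0.663), with 9 members higher, such as Gbp2 (0.34 ± 0.068), and 4 lower, such as Ciita (-0.55 ± 0.053). The regulatory T list (adjusted p = 0.390), the cytotoxic list (adjusted p = 0.626) and the immune privilege list (adjusted p = 0.665, 4 higher and 3 lower of 13) did not pass by camera. Nor did the CCL22 axis list (adjusted p = 0.387, 1 higher and 0 lower of 6). The medians of the immune privilege and CCL22 axis lists were -0.052 and -0.037, while their means and the camera direction were above 0. The type I interferon list fell at a median of -0.15 (8 of 21 lower; 9 adjusted over the list alone; adjusted p = 0.513 with an estimated correlation). That call was lost without loaded-device library 1 (camera adjusted p = 0.0709) and with a stricter filter (0.0920).

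The genes with the highest fold changes between the devices were Ptprq (4.08 ± 0.16), Cyp2e1 (2.33 ± 0.067), the neuronal adhesion gene Cntnap5a (2.21 ± 0.080), the imprinted gene Nnat (2.12 ± 0.17), Edn3, which encodes a growth factor of melanocytes (2.04 ± 0.10), Pck1 (1.79 ± 0.062), Ces1f (1.72 ± 0.14) and Adipoq (1.68 ± 0.054). Those with the lowest were Fetub (-2.83 ± 0.075), the interferon-inducible gene Ifi202b (-2.78 ± 0.085), the water channel gene Aqp5 (-2.70 ± 0.081), Wfdc12 (-2.69 ± 0.14), Saa1 (-2.38 ± 0.13), Tmprss11b (-2.33 ± 0.13), Sprr2i (-2.33 ± 0.10) and the homeobox gene Pitx1 (-2.11 ± 0.11). Ces1f, Ifi202b and Sprr2i have close copies and are uncertain. edgeR called 10805 genes (5971 higher, 4834 lower, 55.3% higher), of which 513 reached 2-fold (207 higher, 306 lower); upper-quartile scaling moved the share of higher calls to 44.4%. With the skeletal muscle score as a covariate 2752 genes were called. Camera called 20 of 37 lists, 5 of them with an estimated correlation.

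The empty device was compared with untreated skin to show what the needles alone went with. Hair shaft, melanocyte and cell cycle genes were lower with the empty device. All 26 hair keratin genes fell (also adjusted over the list alone), with a median log2 fold change of -0.51; Krt32 changed by -1.06 ± 0.045, Krt40 by -0.90 ± 0.042 and Krt71 by -0.64 ± 0.042 (n = 3 libraries per group). Keratin-associated protein genes fell in 47 of 55 cases and 3 rose (median -0.56; 48 lower adjusted over the list alone), with Krtap5-3 at -3.76 ± 0.17 and Krtap5-2 at -2.40 ± 0.13. All 20 cell cycle genes fell (also adjusted over the list alone; median -0.68), such as Ccnb1 (-1.23 ± 0.044) and Top2a (-1.06 ± 0.035), and 14 of 15 melanocyte genes fell (14 adjusted over the list alone; median -0.91), such as Slc45a2 (-1.51 ± 0.070). With an estimated correlation the adjusted p of these 4 lists was 0.210, 0.248, 0.114 and 0.194.

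Dermal papilla genes fell in 12 of 17 cases, with 1 higher (13 lower adjusted over the list alone; median -0.47) and adipocyte genes in 10 of 15, with 5 higher (10 lower adjusted over the list alone; median -0.71); with an estimated correlation the adjusted p was 0.194 and 0.211. The summed counts of the adipocyte list went the other way, at 0.237 ± 0.00170% of counts in untreated skin, 0.265 ± 0.0165% with the empty and 0.275 ± 0.00568% with the loaded device. Its higher members were Car3 (0.49), Slc2a4 (0.49), Acsl1 (0.45), Pnpla2 (0.16) and Lipe (0.15), named after their values were seen. Car3 and Slc2a4 are also expressed in skeletal muscle. The hair matrix list fell at a median of -0.25 (16 of 23 lower and 3 higher; 18 lower adjusted over the list alone; adjusted p = 0.686 with an estimated correlation). This call was lost without empty-device library 3 (camera adjusted p = 0.170) and without untreated library 3 (0.0960). It was also lost with DESeq2, upper-quartile or library-size scaling (0.0604, 0.123 and 0.210), with a stricter filter (0.231), and with the skeletal muscle score as a covariate, where its direction turned (0.901). Skeletal muscle genes rose in 16 of 20 cases and fell in 2 (16 higher adjusted over the list alone; median 0.38; adjusted p = 0.520 with an estimated correlation), and the muscle regulator gene Myod1 changed by 1.24 ± 0.13. With the muscle score, which is built from such genes, as a covariate, the list turned in direction (camera adjusted p = 0.834) and the Myod1 call was lost (edgeR adjusted p = 0.174).

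Interferon-gamma response, type I interferon, macrophage, fibroblast and MHC class I genes were lower with the empty device. Of 21 interferon-gamma response genes 16 fell and 2 rose (median -0.63; 18 lower adjusted over the list alone), with Cxcl9 at -2.37 ± 0.090 and Cxcl10 at -1.90 ± 0.12; of 21 type I interferon genes 15 fell (median -0.37; 16 adjusted over the list alone), with Ifit1 at -2.08 ± 0.074. The adjusted p was 0.194 and 0.194 with an estimated correlation. In each of the 2 interferon lists, 15 of 21 members fell with both devices. Both comparisons use the same 3 untreated libraries, so a fall with both devices here and below is not 2 independent results. Mmp12, which encodes macrophage elastase, fell from 35.7 ± 0.811 to 5.30 ± 0.0866 CPM, and the macrophage list fell in 13 of 19 cases and rose in 2 (median -0.41; 14 lower adjusted over the list alone; adjusted p = 0.319 with an estimated correlation). Fibroblast and matrix genes fell in 17 of 23 cases and rose in 2 (17 lower adjusted over the list alone; median -0.21; adjusted p = 0.319 with an estimated correlation), and 16 members fell with both devices. MHC class I genes fell in 10 of 17 cases and rose in 3 (10 lower adjusted over the list alone; median -0.25; adjusted p = 0.616 with an estimated correlation), and 10 fell with both devices. The MHC class I call was lost without empty-device library 1 (camera adjusted p = 0.0648), with library-size scaling (0.0698) and with a stricter filter (0.124). Ligand and receptor genes of the CCL22 axis fell in 4 of 6 cases, also adjusted over the list alone (median -0.66; adjusted p = 0.209 with an estimated correlation), including Ccl17 (-2.31 ± 0.25) and Ccl22 (-0.85 ± 0.088). That call was lost with a stricter filter (camera adjusted p = 0.118) and with the skeletal muscle score as a covariate (0.0623). MHC class II genes did not pass (camera adjusted p = 0.418), with 4 members higher, such as Cd74 (0.41 ± 0.036), and 3 lower. Nor did the cytotoxic list (camera adjusted p = 0.495), with 6 of 18 members lower, 0 higher and a median of -0.39.

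The injury list fell in 13 of 24 cases and 2 rose (13 and 2 adjusted over the list alone; median -0.25; adjusted p = 0.616 with an estimated correlation). Krt6b stood at 214 ± 20.2 CPM with the empty device, against 641 ± 50.1 in untreated skin. The camera call of the injury list was lost with the muscle score as a covariate (0.414). The epidermal differentiation list did not pass (camera adjusted p = 0.0970), and its median of -0.10 lay below 0 while its mean and the camera direction were above 0; 10 members rose, led by Krt2 (1.86 ± 0.070) and Lor (0.88 ± 0.042), and 10 fell, led by Klk7 (-0.57 ± 0.039). It passed, higher, without empty-device library 2 (0.0169) or 3 (0.00843), with DESeq2, upper-quartile or library-size scaling (0.0484, 0.0446 and 0.0250) and with the skeletal muscle score as a covariate (0.000404). The other genes with the highest fold changes were Morc1 (2.04 ± 0.15), Sprr2i (1.43 ± 0.093), the citrullinating enzyme gene Padi2 (1.30 ± 0.078), the type 2 response gene Retnla (1.28 ± 0.070), Atp1b4 (1.19 ± 0.16; not called with the muscle score as a covariate, adjusted p = 0.366) and Ankdd1a (1.17 ± 0.070). Those with the lowest also held Ighv7-3 (-6.39 ± 0.32), Cxcl11 (-3.10 ± 0.18) and Ighg1 (-2.43 ± 0.076). edgeR called 12597 genes (5258 higher, 7339 lower, 41.7% higher), of which 607 reached 2-fold (171 higher, 436 lower). The share of higher calls was 57.9% with scaling by library size alone, which moved the median of all genes by 0.10 on the log2 scale. Upper-quartile scaling called 6902 genes higher and 6109 lower, and 4415 genes were called with the skeletal muscle score as a covariate. Camera called 18 of 37 lists, of which 0 passed with an estimated correlation (8 at an unadjusted p under 0.05; fry called 32).

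**Figure D4:**
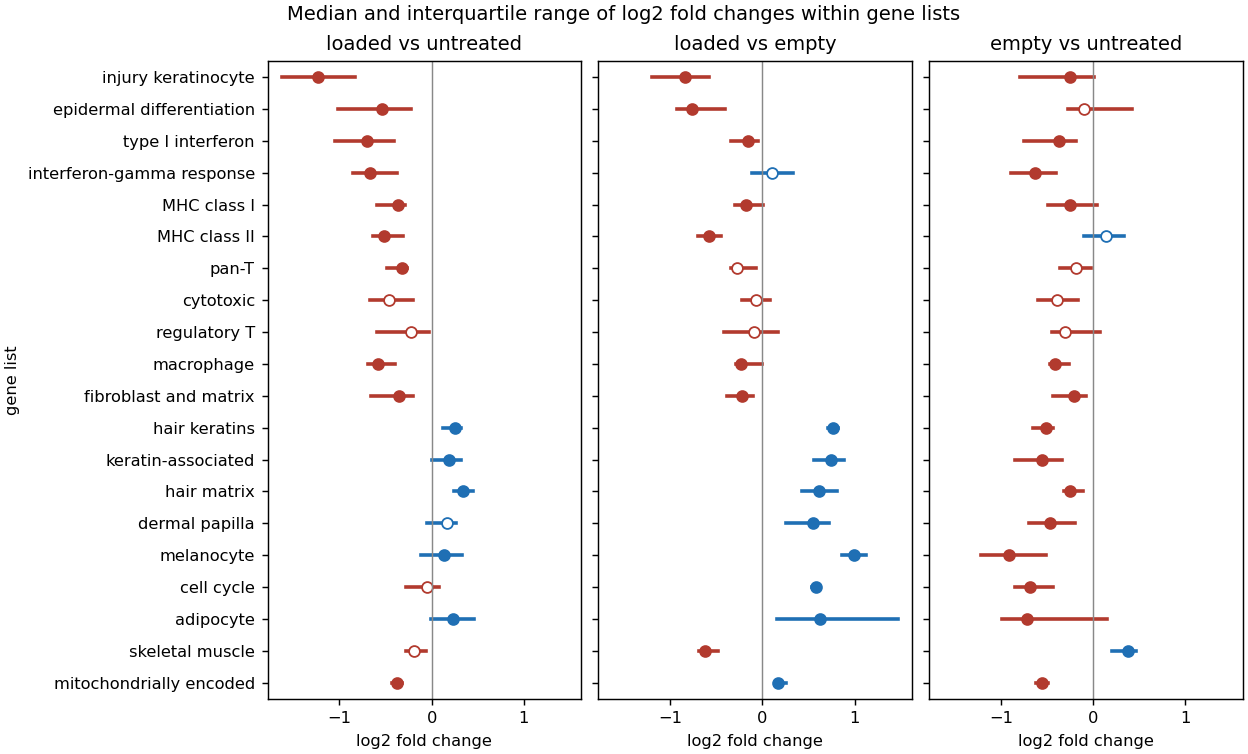
Median (point) and interquartile range (line) of log2 fold changes (x axis) within 20 gene lists (y axis), 1 panel per comparison; blue is above 0 and red below, and a filled point marks a camera adjusted p under 0.05 at the preset correlation. The hair keratin, keratin-associated protein, hair matrix, melanocyte and adipocyte lists lie above 0 in both comparisons of the loaded device and below 0 with the empty device, and the type I interferon list lies below 0 in all 3.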

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

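The tests of V genes and of the hair follicle pattern, and the counts of genes in other splits, were chosen or written down only after the results were seen; the counts of lists in other splits were written down before. The tests of muscle RNA and of fewer follicles replaced others after their results were seen. The muscle test replaced a bound from the share of counts of the listed muscle genes, which leaves out other muscle transcripts, and a comparison with basal keratinocyte genes, a list picked after its values were seen. The test of fewer follicles replaced a first one after its result was seen, in which the lower quartile of the follicle stem cell list lay 0.19 above the upper quartile of the hair keratin list on the log2 scale, for the empty device against untreated skin. 5 lists were called in opposite directions with the 2 devices against untreated skin, and differed between the devices by camera. Their median log2 fold changes, loaded against empty device, were 0.76 for hair keratins, 0.74 for keratin-associated proteins, 0.62 for the hair matrix, 0.99 for melanocytes and 0.62 for adipocytes. With an estimated correlation the difference held for melanocytes and adipocytes (adjusted p = 0.0288 each) and not for the other 3 (adjusted p = 0.0505, 0.0721 and 0.0631), and none of the calls against untreated skin held with it. The melanocyte call with the loaded device was lost without loaded-device library 1 or 2 or untreated library 2 or 3 (camera adjusted p = 0.0608, 0.0571, 0.0669 and 0.0510). The hair matrix call with the empty device was lost without empty-device library 3 or untreated library 3 (0.170 and 0.0960), under 3 of the 5 scalings, with a stricter filter (0.231) and with the muscle score as a covariate (0.901).

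The hair keratin, keratin-associated protein and melanocyte lists were lower with the empty device than in both other groups. The choice among the 5 scalings did not remove this pattern, since the medians of these lists against untreated skin lay at or below -0.41 under each. These scalings moved fold changes by a median of up to 0.10 from the main one on the log2 scale. They therefore could not test a larger error of scaling, which stays open. RNA from skeletal muscle stays open: with the muscle score as a covariate the medians went from -0.51, -0.56 and -0.91 to -0.29, -0.33 and -0.77, and without empty-device library 1 they were -0.12, -0.15 and -0.49, with an upper quartile of 0.11 for the keratin-associated proteins. Fewer follicles in the sampled skin stay open: 70.4% of the 95% intervals of hair shaft genes excluded their common median of -0.52, but these intervals leave out any spread between animals. The empty device itself may lower these genes (median -0.51), but so may the skin that was sampled, and the 2 cannot be told apart because the labels do not say that the libraries of a group came from separate animals.

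The libraries of a group were closer to each other than to those of other groups. Their median index over genes was 1.90 to 3.91 (means of up to 12.8), where counting noise gives 1 if all counts are independent. No column of counts is a copy of another in its group, since the lowest of these medians is 1.90. Whether 1 library was sequenced several times stays open. It is not given whether reads or fragments were counted, and paired reads counted singly would raise counting noise above 1. A candidate explanation is that the libraries of a group share 1 source of RNA, such as 1 animal or 1 pool. Over 32 V genes of antibody and T cell receptor loci the index was 1.64 within groups and 30.3 between groups, against medians of 1.60 and 2.47 over 1000 sets of other genes matched on count. The highest index between groups in any of those sets was 5.88, so V genes differed between groups more than every matched set. The rank alone does not set V genes apart, because the real grouping had the lowest index within groups in 81.4% of those sets as well. A shared source stays open, because no libraries known to come from separate animals show what V genes give there, and treatment, animal and sampled site go with the same groups.

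Of 100 splits of the 9 libraries into 3 groups of 3, drawn from 280, 1 gave as many genes as the 3-group test, the real one with 15440, and the highest of the others gave 4419. Chance can be excluded for this count only as far as the libraries of a group are independent, and differences between 3 animals or pools are not excluded. For the pairwise counts the 10 possible splits are too few for a share under 0.05. The real splits called 11024, 10805 and 12597 genes (1 of 10 splits each), and the others called 0 genes each by edgeR, with up to 609, 703 and 811 genes at an unadjusted p under 0.05. For lists, 3, 2 and 1 of the 10 splits called as many as the real ones with 17, 20 and 18, and the highest other splits called 22, 21 and 14 lists, for the loaded device against untreated skin, the loaded against the empty device and the empty device against untreated skin.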

How the results depend on the processing

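The test against a 2-fold change was chosen after seeing the data, and the other alternatives before. Counts of called genes stayed within 1.5 times the main count under every scaling, filter and tool tried and on leaving out each library. Which genes were called was less stable. Library-size scaling kept 80.9% of the main calls for the loaded device against untreated skin, and called 8487 genes higher and 3973 lower. Upper-quartile scaling turned the majority to lower between the devices (4782 higher, 5982 lower). For the empty device against untreated skin it turned the majority to higher (6902 higher, 6109 lower). In these cases no call shared with the main fit changed sign. A 2-fold minimum left 501, 513 and 607 genes for the loaded device against untreated skin, the loaded against the empty device and the empty device against untreated skin, and a test against a 2-fold change left 105, 84 and 102, by the construction of these tests. With the muscle score as a covariate 2752 genes and 13 lists were called between the devices and 4415 genes between the empty device and untreated skin; the cause was not tested, though the score differs between these groups more than within them. The same covariate turned the direction of the hair matrix and skeletal muscle lists between the empty device and untreated skin. Both were then not called (camera adjusted p = 0.901 and 0.834), and the score is built from the genes of the muscle list itself. With an estimated correlation, camera called 0, 5 and 0 lists, with 11, 11 and 8 at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 30, 34 and 32; the cause was not tested. With the replicate number as a block, 10960, 10753 and 12490 genes and 15297 in the 3-group test were called, and 20, 20 and 18 lists. Deviations of libraries with the same number correlated at -0.019 to 0.015, and those with different numbers at -0.023 to 0.031. No pairing by number was seen. A pairing is not excluded, since libraries of a group that share a source would carry no animal effect in these deviations. Among single results, 1691 gene values kept their side of the threshold and 81 lost it. These are values of the genes with the 8 highest and 8 lowest called fold changes and of those fixed by name. Since many were picked for large changes, the counts do not show how called genes in general would hold. Of the list values 1518 kept their side, 79 lost it, 66 gained it and 2 turned. Genes near the detection limit, such as Il2 and Foxp3, had too few counts for small differences to be detected.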

Other observations

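Lists not described in the comparisons gave these values. Immediate-early and heat shock genes were higher with both devices than in untreated skin, in 9 of 15 cases with the loaded device and 2 lower (median 0.20, adjusted p = 0.152 with an estimated correlation) and 11 with the empty device and 2 lower (median 0.22, 0.194), with Fos at 1.03 and 0.99. Mitochondrially encoded genes were lower with both, in 10 and 12 of 13 cases (medians -0.37 and -0.55; adjusted p = 0.248 and 0.209 with an estimated correlation). Between the devices they were higher with the loaded one, in 9 of 13 cases with 0 lower (median 0.17; adjusted p = 0.513 with an estimated correlation), a call lost with a stricter filter (camera adjusted p = 0.0591). Type 2 cytokine genes were lower with the loaded device, in 6 of 14 cases with 1 higher against untreated skin and in 8 with 0 higher against the empty device, at medians of -0.44 and -0.36 (adjusted p = 0.248 and 0.194 with an estimated correlation), among them Il33 (-1.08 and -0.46); the call between the devices was lost with the muscle score as a covariate (camera adjusted p = 0.147). Between the devices camera called the basal keratinocyte list lower and the follicle stem cell list higher, at medians of -0.14 (6 of 10 lower, 0 higher) and 0.25 (10 of 16 higher, 3 lower; adjusted p = 0.231 and 0.391 with an estimated correlation, in this order). The basal call was lost with the muscle score as a covariate (camera adjusted p = 0.0770). The stem cell call was lost without empty-device library 3 (camera adjusted p = 0.113), with DESeq2 or upper-quartile scaling (0.0657 and 0.104), with a stricter filter (0.168) and with the muscle score as a covariate (0.416). Between the empty device and untreated skin this list did not pass (0.116), but did without untreated library 1 (0.0453). The lists for gamma-delta T cells, checkpoint genes, dendritic cells, neutrophils, mast cells, B and plasma cells, sebaceous gland, endothelium, Schwann cells and red blood cells did not pass in any comparison with TMM scaling and all 9 libraries (camera adjusted p of 0.0575 to 0.963). The dendritic cell list passed between the loaded device and untreated skin without untreated library 1 (0.0462) or loaded-device library 3 (0.0383) and with library-size scaling (0.0401). The neutrophil list passed there with library-size scaling (0.0192) and with a stricter filter (0.00451). The Schwann cell list passed between the devices without empty-device library 1 (0.0384). Lyve1, a member of the endothelial list, was lower with the loaded device (-1.35 against untreated skin and -1.32 against the empty device). That list had 3 of 17 members higher and 3 lower against untreated skin, and 0 higher and 5 lower against the empty device. The cell type behind the Lyve1 change was not tested.

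Of genes called with both devices against untreated skin, 4295 were lower in both, 2309 higher in both and 1511 opposite, against 1709, 998 and 2617 for independent lists of these sizes. Over 20 simulated sets of unchanged groups that share the untreated libraries, the means were 0, 0.05 and 0. Unchanged groups give almost no called genes, so these means cannot show what the shared libraries add to the overlap of calls. The correlation of the fold changes over genes, which are not independent replicates, was 0.526, against 0.519 in the simulations, and their covariance was 0.0989, against 0.0218, a difference of 0.0770. With 3 untreated libraries they could not be split into parts of at least 2 each, so the excess over independent lists includes any part that the shared libraries add.

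For lists added after the counts were seen, no test was run. For clock genes that peak with Arntl and for those of opposite phase, the medians were 0.18 and 0.05 for the loaded device against untreated skin, -0.32 and 0.01 between the devices, and 0.05 and 0.03 for the empty device against untreated skin. For 16 p53 target genes other than Mdm2 they were -0.0023, -0.028 and -0.072 in the same order.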
